A study of Danio rerio with 6 samples.

How the data were processed

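Poly(A) RNA of fin tissue, with an RNA integrity number above 7.0, was sequenced as paired reads of 150 bases on an Illumina NextSeq instrument, per the labels' protocols. The deposited table holds raw counts per gene entry for 3 control and 3 ZnO libraries, made by the authors and not normalized. Per the submitters' processing notes, cutadapt, BWA, HTSeq and DESeq2 were used with the GRCz11 genome. Their versions and settings, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. BWA is not a splice-aware aligner, and how spliced reads were handled is not given either, so counts of entries with many short exons, overlapping entries and near-identical copies are less certain. The labels state 5 fish per group in triplicate, each in 150 mL of water, without saying how fish relate to libraries.

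The table has 53709 entries, of which 14856 had 0 counts in all libraries. A numeric suffix after the symbol marks 7246 entries other than transfer RNA, and 6201 names have 2 or more entries, which hold 23.2% ± 0.232 of control and 24.0% ± 0.514 of ZnO counts (SD, n = 3). Entries were analysed as deposited. All columns of the table were matched to samples by name, and no entry was a total or unassigned class. Names were checked against a RefSeq gene table of another assembly (GRCz12tu), used for names and synonyms only: 31415 entries matched by symbol and 46979 after a suffix was removed. Genome coordinates are not used here.

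Entries were filtered with filterByExpr (minimum count 10), leaving 25962, which hold 99.9% of counts. Libraries were scaled by TMM (factors 0.981 to 1.02) and tested with edgeR's quasi-likelihood test (robust, groups only), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.221. Levels are TMM-scaled CPM with SD over 3 libraries, and log2 fold changes carry SE. Gene lists were tested with camera on the same fit, 2-sided, with a preset inter-gene correlation of 0.01 and adjustment over 35 lists. No list call holds with an estimated correlation, and 0 lists pass fry, which asks whether a list's genes move one way on balance. Log CPM used a prior count of 2. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

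The groups, the test, 16 single genes, 35 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each direction, the 7 entries with the largest change and the 7 with the smallest p among those past the threshold with non-overlapping groups, mean CPM of at least 1 and a symbol that is not a clone or locus name. It adds up to 4 members of each list past the threshold and the 16 genes whatever their result. Other genes are named as examples of list members past the test over their list alone, or were chosen after their values were seen (hbaa1, nr1d1, per1b, clocka, krt5_1, ftr43, ftr50 and second entries of named genes). Of 1565 list members written, 1502 had an entry, by symbol or a unique synonym. No duplicate library was found.

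Alternatives were DESeq2, limma-voom with and without sample weights, other scalings, other filters, the replicate number as a block, each library left out, a minimum 2-fold change and an adjusted p under 0.01. Summing entries of a symbol and a clock covariate were added after the data were seen. The covariate was the mean log2 CPM of per1a, per1b, per3, nr1d1 and ciarta in each library, genes picked because their levels differed between libraries, and 1 such index was tried. The scripts were tested on simulated data, with counts for the filtered entries drawn at the observed means and depths. About 25500 were left when the filter was applied again. For ZnO against control, 20% of entries changed 1.5-fold, 72% of those changed 2-fold and 100% of those changed 4-fold or 8-fold were recovered. Of about 25300 unchanged entries 8 were called. Changed entries were drawn only from those with higher counts, and the spread followed a smooth trend without gene-specific or library-wide differences. Recovery in the real data can therefore be lower: hsp70l had a log2 fold change of 2.67 and did not pass (edgeR adjusted p = 0.108).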

Results

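Messenger RNA was measured in the tail fin blastema of male zebrafish, Danio rerio, 4 days after amputation. A blastema is the mass of proliferating cells from which a cut fin regrows. Fish of 1 group were kept in water containing 2 mg/L zinc oxide nanoparticles made with a propolis extract, called ZnO here, and fish of the other in distilled water. Each group had 3 libraries, with 26624174 to 31712994 counts per library. Controls averaged 30259800 counts and ZnO libraries 28236400, and 1 count corresponded to between 0.0315 and 0.0376 CPM (counts scaled to a library total of 1000000). The labels do not say whether a library came from 1 fish or from several, so p-values measure the spread between these samples. The comparison asks which transcripts of the regenerating fin differ in fish kept with the nanoparticles. No group received the propolis extract or dissolved zinc alone, so their parts cannot be told apart from that of the particles.

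Among entries past the threshold, more were lower than higher in the ZnO libraries. gig2l, a member of a fish interferon-induced gene family, fell from 20.07 ± 7.77 CPM in controls to 0.587 ± 0.25 in ZnO (SD, n = 3 each). The flow-responsive transcription factor klf2a fell from 768 ± 38 to 194 ± 45.7 CPM, and cfbl, a complement factor B-like gene, from 49.3 ± 3.70 to 10.7 ± 2.94. Among the higher entries, mt2, a zinc-binding metallothionein, rose from 4.81 ± 0.801 to 16.5 ± 3.93 CPM, and selenop, the plasma selenium carrier, from 84.8 ± 14.5 to 229 ± 38.2. The naming rule also took the lower entries abcb4 (log2 fold change -3.75 ± 0.51, SE), gig2q (-3.15 ± 0.50) and alox5b.3 (-2.95 ± 0.30). On the higher side it took rasgrf2b (1.76 ± 0.28), stc2a_1 (1.33 ± 0.18) and upk3b_1 (0.86 ± 0.12). In all, 25 of 25962 tested entries were higher and 86 were lower in ZnO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 77.5% of the 111 calls were lower. This imbalance was confined to the calls. Over all tested entries the median log2 fold change was 0.0148, and at an unadjusted edgeR p under 0.05, 2003 were higher and 2129 lower. The 111 entries carry 102 distinct names, because the table holds several entries for some symbols. Groups did not overlap at any of the 111, which selection by a small p with 3 libraries per group nearly fixes, so it adds no support. Among all tested entries 22.5% did not overlap, against 10% by chance. The number of calls depended on single libraries: higher and lower entries numbered 2 and 32 without control 1, 4 and 29 without control 2, 0 and 25 without control 3, 87 and 282 without ZnO 1, 2 and 26 without ZnO 2, and 0 and 12 without ZnO 3. DESeq2 called 419 higher and 772 lower, among them all 111.

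**Figure D1:**
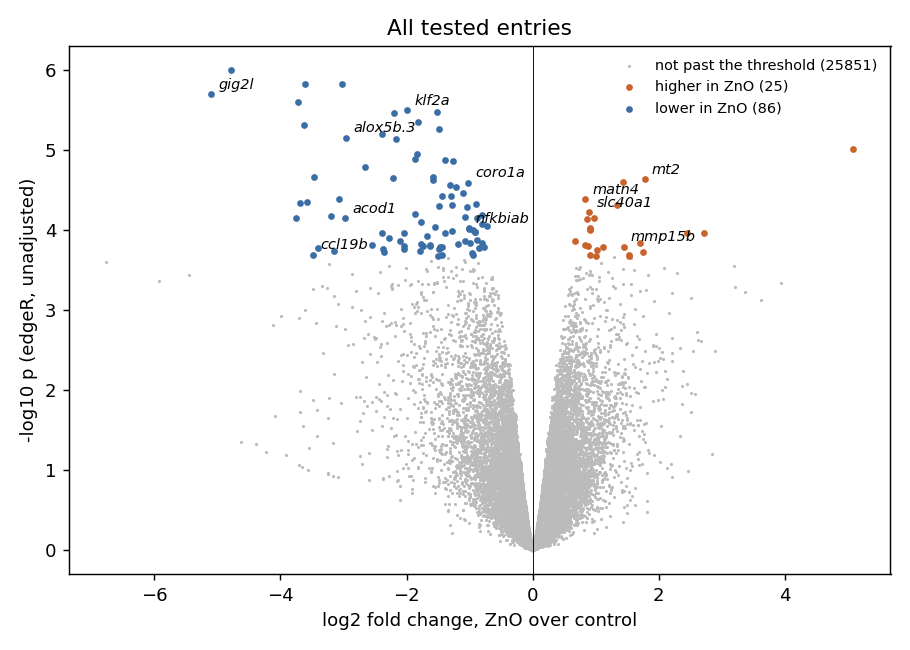
Each point is 1 tested entry, with the log2 fold change of ZnO over control on the x axis and the unadjusted edgeR p as -log10 on the y axis. The 86 entries lower in ZnO and the 25 higher are coloured, and some of the genes named in the text are marked.

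Metal-handling genes were among the higher entries without a general rise of zinc transporters. mt2 had a log2 fold change of 1.78 ± 0.21 (SE; edgeR adjusted p = 0.0249), was higher in each ZnO library than in each control, and rose also when adjusted over the list alone of the 16 genes fixed in advance. The call over all genes ended with any 1 library except ZnO 1 left out (edgeR adjusted p 0.0526 to 0.0867) and with the replicate block (0.0697), with log2 fold changes of at least 1.56. Its second entry, mt2_1, had a log2 fold change of 1.70 (edgeR adjusted p = 0.0675). slc40a1, which encodes the iron exporter ferroportin, rose from 21.0 ± 1.25 to 39.0 ± 4.30 CPM. Of the 13 tested genes of the metallothionein and metal response list, 2 rose over all genes, 4 by DESeq2, while 4 rose and 1 fell when adjusted over the list alone (median 0.16, camera adjusted p = 6.01e-04). The 4 were mt2, slc40a1, tfa and hsp70l, which is also in the heat shock list, and the 1 was slc39a10. Of these tfa was near the floor of detection in controls, at 0.0766 ± 0.0471 CPM, and at 0.998 ± 0.659 in ZnO. The metal response list had a camera adjusted p = 0.350 with an estimated correlation. The zinc exporter gene slc30a1a stood at 50.2 ± 2.09 CPM in controls and 40.5 ± 6.45 in ZnO (log2 fold change -0.31 ± 0.14, edgeR adjusted p = 0.312; -0.19 without ZnO 3 and -0.07 with the clock covariate described with the clock genes), and none of the 19 tested zinc transporters passed by edgeR or DESeq2, where the whole edgeR test had 4132 entries at an unadjusted p under 0.05 (median -0.07, camera adjusted p = 0.502).

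Heat shock and antioxidant genes moved in both directions. In the heat shock and unfolded protein response list, 0 of 46 genes passed over all genes by edgeR, 7 by DESeq2. Adjusted over the list alone, 4 rose, all of the inducible hsp70 group (hsp70.1, hsp70.2, hsp70.3 and hsp70l), and 3 fell, dnaja1, herpud1 and chac1. hsp70l stood at 2.08 ± 1.48 CPM in controls and 13.2 ± 5.13 in ZnO (edgeR adjusted p = 0.108), and DESeq2 called it over all genes (adjusted p = 1.5e-06). The list's median was -0.23 (camera adjusted p = 0.0326), with an adjusted p = 0.590 with an estimated correlation. Of 41 oxidative stress and Nrf2 genes, txnb, a thioredoxin, fell with a log2 fold change of -1.40 ± 0.16 by edgeR, and DESeq2 called 2 higher and 3 lower. Adjusted over the list alone, mgst1.1 and sod3b rose and txnb, gclm and keap1a fell, and the list median was 0.04 (camera adjusted p = 0.906). The heme oxygenase gene hmox1a was at 19.8 ± 3.07 and 21.5 ± 6.52 CPM (edgeR adjusted p = 0.839).

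Interferon-stimulated and antigen-presentation genes were lower nearly throughout their lists. Of 45 tested interferon response genes, 44 had negative log2 fold changes, with a median of -0.80. mxc, an antiviral Mx GTPase, fell from 217 ± 40.0 to 76.4 ± 22.7 CPM, the 1 member past the edgeR threshold over all genes, where DESeq2 called 18 lower. By edgeR 22 fell when adjusted over the list alone, among them stat1b, irf9, cgasa and ifit9. The list passed camera (adjusted p = 3.27e-21), with an adjusted p = 0.318 with an estimated correlation. In the antigen processing and presentation list, 34 of 36 genes were negative (median -0.50), and erap1b, a peptide-trimming aminopeptidase, and psme2, a proteasome activator subunit, fell by 0.88 and by 0.80 on the log2 scale by edgeR, where DESeq2 called 12 lower. Adjusted over the list alone, 16 fell, including b2m at 1009 and 594 CPM and the class I gene mhc1uba at 1871 and 849, and rfxap rose. The camera adjusted p = 3.67e-15 became an adjusted p = 0.386 with an estimated correlation.

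Neutrophil markers were lower as a group. All 22 were negative, with a median log2 fold change of -1.02. Over all genes 4 fell: ncf4, a subunit of the phagocyte NADPH oxidase, from 11.63 ± 2.40 to 3.89 ± 0.346 CPM, coro1a, a leukocyte actin regulator, from 48.3 ± 5.14 to 23.7 ± 1.97, mmp25b, a matrix metalloproteinase, from 11.9 ± 0.835 to 3.50 ± 1.16, and csf3r, the granulocyte colony-stimulating factor receptor, from 50.4 ± 8.0 to 18.6 ± 5.84. The second entry of ncf4, ncf4_1, was at 5.74 ± 1.58 and 4.30 ± 1.48 CPM with overlapping groups (log2 fold change -0.41, edgeR adjusted p = 0.534), and the sum of both had -1.09. Adjusted over the list alone 15 fell, and DESeq2 called 11 over all genes. The list had camera adjusted p = 6.42e-19 and adjusted p = 0.229 with an estimated correlation. Myeloperoxidase, mpx, stood at 185 to 286 CPM in controls and at 60.3, 4.71 and 54.2 in the ZnO libraries (edgeR adjusted p = 0.264, DESeq2 0.0956), and without ZnO 2, the lowest library, edgeR called it (log2 fold change -2.04, adjusted p = 0.038, range over alternatives 0.038 to 0.907). The macrophage list had a median of -0.50 with 6 of 28 genes lower when adjusted over the list alone and 0 over all genes by edgeR, against 6 by DESeq2 (camera adjusted p = 3.22e-06, adjusted p = 0.553 with an estimated correlation). The macrophage gene mpeg1.1 was at 110 ± 22.3 and 85.2 ± 21.4 CPM. B cell markers had a median of -0.47, with 4 of 16 lower when adjusted over the list alone, among them the immunoglobulin gene ighd, and 4 lower over all genes by DESeq2 (camera adjusted p = 2.42e-04, adjusted p = 0.308 with an estimated correlation). T cell and natural killer-like markers had a median of -0.41 with 0 of 32 past the edgeR threshold and 1 by DESeq2 (camera adjusted p = 0.00390, adjusted p = 0.590 with an estimated correlation).

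**Figure D2:**
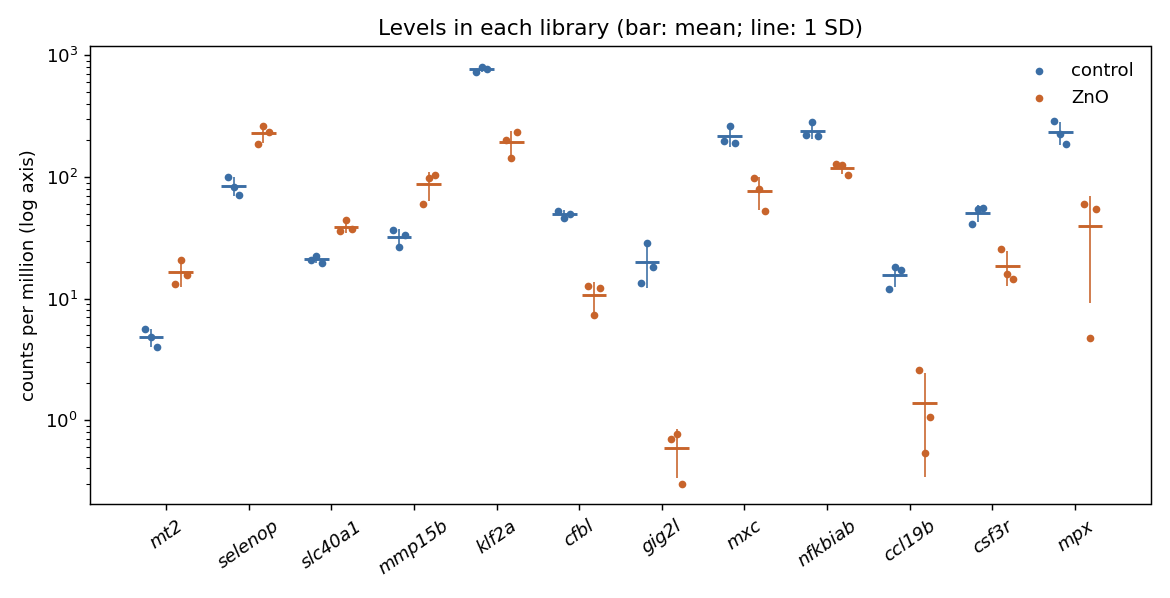
CPM on a log axis for 12 genes in each of the 3 control and 3 ZnO libraries, with the mean as a bar and 1 SD as a line. klf2a lay between 729 and 805 in controls and between 144 and 234 in ZnO, while mpx ranged from 4.71 to 60.3 in ZnO.

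Inflammatory signalling genes were lower in part. ccl19b, a chemokine, fell from 15.7 ± 3.27 to 1.39 ± 1.05 CPM, and acod1, the itaconate-producing enzyme of activated macrophages, from 19.2 ± 5.69 to 2.43 ± 1.24. Of 55 cytokine and chemokine genes, 1 fell over all genes by edgeR, against 10 lower and 1 higher by DESeq2, and 9 fell and 1 rose, cxcl8b.1, when adjusted over the list alone (median -0.34, camera adjusted p = 2.19e-04, adjusted p = 0.388 with an estimated correlation). il1b stood at 41.2 ± 18.5 and 12.4 ± 3.76 CPM (edgeR adjusted p = 0.130) and tnfa at 1.94 ± 1.13 and 0.461 ± 0.216 (edgeR adjusted p = 0.122), and both fell when adjusted over the list alone of fixed genes (edgeR, 0.0152 each). DESeq2 called both over all genes (adjusted p = 5.78e-05 and 0.00714), and edgeR called il1b without control 3 (adjusted p = 0.0469, range over alternatives 5.78e-05 to 0.842). cxcl8a was at 1.91 ± 0.666 and 1.9 ± 0.522 CPM. In the Toll-like receptor and NF-kB list, bcl3 and nfkbiab, inhibitor-type regulators of NF-kB, fell by 1.48 and by 1.02 on the log2 scale, and 10 of 49 fell when adjusted over the list alone, 9 over all genes by DESeq2 (median -0.25, camera adjusted p = 6.31e-08, adjusted p = 0.386 with an estimated correlation). The acute phase and antimicrobial list had a median of -1.44, with 6 of 12 genes lower when adjusted over the list alone, acod1 over all genes by edgeR and 5 by DESeq2 (camera adjusted p = 6.31e-08, adjusted p = 0.229 with an estimated correlation). Among 21 complement genes c1s.1 and c6.2 fell, where DESeq2 called 5 lower and 2 higher of 24, and 6 fell and 2 rose when adjusted over the list alone (median -0.36, camera adjusted p = 0.00112, adjusted p = 0.475 with an estimated correlation). JAK-STAT genes had a median of -0.16, with 7 lower and 2 higher of 34 when adjusted over the list alone, 0 over all genes by edgeR and 7 by DESeq2 in either direction (camera adjusted p = 0.0249, adjusted p = 0.553 with an estimated correlation). Of 41 immediate early genes klf2a fell by edgeR, where DESeq2 called 8 lower and 1 higher, and 9 fell and 2 rose when adjusted over the list alone (median -0.40, camera adjusted p = 5.56e-08, adjusted p = 0.388 with an estimated correlation). Among p53 and apoptosis genes 2 of 51, mcl1b and faslg, fell when adjusted over the list alone, and 0 over all genes by edgeR against 3 by DESeq2 (median -0.15, camera adjusted p = 0.0432, adjusted p = 0.590 with an estimated correlation).

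Blastema and proliferation genes fixed in advance did not pass over all genes. fgf20a, needed to start blastema formation, stood at 1.74 ± 1.1 CPM in controls and 1.79 ± 0.367 in ZnO, and its more abundant entry fgf20a_1 at 4.65 ± 1.66 and 4.95 ± 1.47. msx1b, a blastema transcription factor, was at 76.2 ± 8.07 and 86.1 ± 14.1, and pcna, a DNA replication factor, at 237 ± 21.6 and 243 ± 12.4. aldh1a2, which makes retinoic acid, was at 4.04 ± 1.28 and 2.68 ± 0.299 CPM, its more abundant entry aldh1a2_1 at 19.7 ± 4.70 and 16.9 ± 2.51 (log2 fold change of the sum -0.27), and tgfb1a at 81.8 ± 9.78 and 84.8 ± 6.59. None of these passed, which does not show that their levels are equal. The log2 fold change of fgf20a was 0.05 ± 0.43 (SE) and ran from -0.24 to 0.69 over alternatives. Of 73 blastema and regeneration factors 0 passed over all genes by edgeR and 4 by DESeq2, while igfbp1a, igf2b and tncb fell when adjusted over the list alone (median 0.05, camera adjusted p = 0.596). The blastema list passed camera in 1 of 12 alternatives (lowest camera adjusted p = 0.0181). None of 74 cell cycle genes passed by edgeR or DESeq2 (median 0.02, camera adjusted p = 0.728). In the extracellular matrix and matrix protease list of 68 genes, mmp15b, a membrane-type metalloproteinase, rose from 32.1 ± 5.02 to 87.2 ± 23.7 CPM and timp2b, a metalloproteinase inhibitor, fell from 72.6 ± 6.17 to 38.5 ± 5.54, with 2 higher and 2 lower when adjusted over the list alone, and 2 higher and 5 lower by DESeq2 over all genes (median 0.11, camera adjusted p = 0.813). mmp9, a gelatinase, was at 260 ± 53.4 and 164 ± 24.3 CPM and mmp13a, a collagenase, at 28.8 ± 6.07 and 20.3 ± 2.26 (edgeR adjusted p = 0.136 and 0.215), and both fell when adjusted over the list alone of fixed genes (edgeR, 0.0152 and 0.0477). DESeq2 called mmp9 over all genes (adjusted p = 0.0184) and not mmp13a (0.143). matn4, a matrilin gene of the extracellular matrix, rose by a log2 fold change of 0.83 ± 0.11, and col13a1, a transmembrane collagen, by 1.53 ± 0.25.

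Markers of other cell types shifted beside these groups. Erythrocyte markers had a median log2 fold change of 1.38 with 18 of 20 positive, and 6 rose when adjusted over the list alone, among them alas2 and slc4a1a, with 0 over all genes by edgeR and 6 by DESeq2 (camera adjusted p = 5.59e-09, adjusted p = 0.386 with an estimated correlation). The globin gene hbaa1 was at 42.4, 8.10 and 50.3 CPM in controls and 51.7, 162 and 109 in ZnO. Osteoblast and bone matrix genes had a median of 0.22, with bglap (osteocalcin) higher when adjusted over the list alone and 0 of 31 over all genes by edgeR, 3 by DESeq2 (camera adjusted p = 2.19e-04, adjusted p = 0.590 with an estimated correlation). Endothelial markers had a median of 0.23, with 1 higher by DESeq2 (camera adjusted p = 0.0432, adjusted p = 0.580 with an estimated correlation) and pigment cell markers of 0.19, with 3 higher by DESeq2 (camera adjusted p = 0.0475, adjusted p = 0.590 with an estimated correlation). Epidermal keratinocyte markers had a median of 0.09, with 3 higher and 4 lower by DESeq2 (camera adjusted p = 0.555), and the keratin entry krt5_1 took 3.02% ± 0.458 of counts in controls and 3.80% ± 0.558 in ZnO. Osteoclast (-0.01, camera adjusted p = 0.661), nerve and glia (-0.13, camera adjusted p = 0.379) and skeletal muscle markers (-0.15, camera adjusted p = 0.794; mean 0.01) did not pass. Over 12 alternatives the endothelial list passed in 6 and the pigment cell list in 5, both lost with the stricter filter, the replicate block, the clock covariate and without control 2 or ZnO 2, the first also without ZnO 1 and the second without control 1 or ZnO 3. With the covariate the pigment cell median was -0.09. Of the other lists that passed, p53 and clock genes passed in 7, T cell markers in 8, heat shock genes in 9 and JAK-STAT genes in 10, and the rest in at least 11. All 12 alternatives kept the preset correlation, and no list passed with an estimated correlation or with fry.

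**Figure D3:**
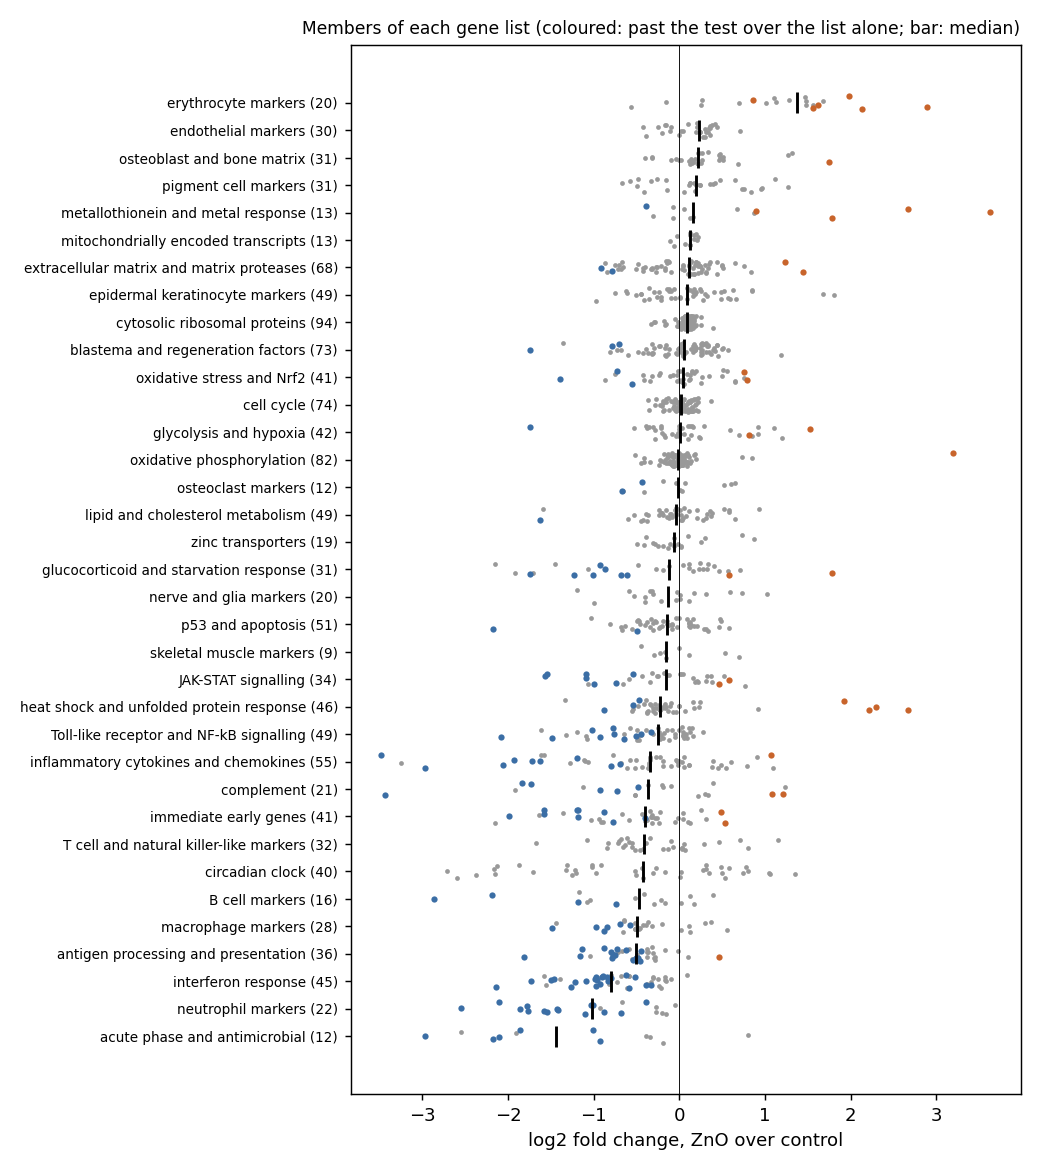
The log2 fold change of ZnO over control (x axis) of each tested member of the 35 gene lists, with the number tested in brackets and the list median as a bar. Coloured members passed when adjusted over the list alone; all 22 neutrophil markers lie below 0.

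Single metabolic genes passed, while no metabolic list passed camera. p4ha1b, a collagen prolyl hydroxylase subunit, rose from 12.1 ± 2.05 to 34.7 ± 10.9 CPM and egln2, an oxygen-sensing prolyl hydroxylase, from 3.58 ± 0.562 to 11.63 ± 3.61. In the glycolysis and hypoxia list of 42 genes p4ha1b rose, with 2 higher and 1 lower when adjusted over the list alone and as many by DESeq2 over all genes (median 0.00, camera adjusted p = 0.555). fads2, a fatty acid desaturase, fell from 11.5 ± 3.75 to 3.73 ± 0.441 CPM within 49 lipid and cholesterol genes (median -0.04, camera adjusted p = 0.502). pah, phenylalanine hydroxylase, rose from 58.7 ± 5.93 to 115 ± 14.8 CPM. Oxidative phosphorylation genes had a median of -0.01 over 82 genes (camera adjusted p = 0.728), mitochondrially encoded transcripts of 0.13 over 13 (camera adjusted p = 0.261) and cytosolic ribosomal protein genes of 0.09 over 94 (camera adjusted p = 0.107). These calls depended on the fit: oxidative phosphorylation and the lipid list each passed in 2 of 12 alternatives and the ribosomal list in 3. With the clock covariate the first had a median of -0.20 with 76 of 82 negative (camera adjusted p = 1.48e-04) and the second of -0.28 (camera adjusted p = 0.0164), both with an adjusted p = 0.842 with an estimated correlation.

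Circadian clock genes ranged widely between libraries, within groups as well as between them. The clock repressor gene per1b stood at 181, 111 and 61.1 CPM in controls 1, 2 and 3 and at 48.2, 3.95 and 1.84 in ZnO 1, 2 and 3. nr1d1, a repressor of the clock activators, was at 60.4, 39.8 and 17.5 CPM in controls and 18.7, 0.268 and 0.468 in ZnO, so that ZnO 1 lay beside control 3 and far from the other ZnO libraries. The activator gene clocka was at 10.6, 15.2 and 22.4 CPM in controls and 20.7, 39.0 and 40.8 in ZnO. None of the 40 clock genes passed by edgeR, and DESeq2 called 8 (median -0.43, camera adjusted p = 0.0432, adjusted p = 0.553 with an estimated correlation). Of 31 glucocorticoid and starvation response genes mt2 rose, and 2 rose and 7 fell when adjusted over the list alone, 2 and 6 by DESeq2 over all genes (median -0.12, camera adjusted p = 0.136). That list passed camera in 2 of 12 alternatives (lowest camera adjusted p = 0.00272). ZnO 1 also lay between the groups on the first principal component (37.5% of variance), at 12.3 against -48.7 to -31.1 in controls and 51.5 and 54.4 in the other ZnO libraries. With the mean level of 5 of these clock genes in each library as a covariate, a fit added after the data were seen, edgeR called 0 entries, with 1714 at an unadjusted p under 0.05, and no other tool was run with it. In that fit mt2 had a log2 fold change of 1.495 ± 0.31 and klf2a of -1.95. Of 37 named calls 4 moved by over 1.5 times: col13a1, egln2, p4ha1b and mmp15b, to 1.02, 0.89, 0.84 and 0.84. Just under that bound, acod1 moved from -2.975 to -2.05, mxc from -1.50 to -1.04 and csf3r from -1.43 to -0.99. Other immune calls moved little or grew, such as gig2l from -5.10 to -4.87 and ncf4 from -1.58 to -1.78. List medians moved from -1.02 to -0.66 for neutrophil markers, -0.80 to -0.66 for interferon genes, -1.44 to -0.56 for the acute phase list, 1.38 to 0.40 for erythrocyte markers, -0.41 to -0.15 for T cell markers and -0.40 to -0.15 for immediate early genes. Osteoblast genes moved from 0.22 to 0.13, JAK-STAT genes from -0.16 to -0.10 and the clock list, which holds the genes of the covariate, from -0.43 to 0.02. B cell markers moved from -0.47 to -0.65, complement from -0.36 to -0.36, Toll-like receptor and NF-kB genes from -0.25 to -0.21 and antigen presentation from -0.50 to -0.40. With the preset correlation 14 lists passed camera in that fit, among them the neutrophil (adjusted p = 6.99e-08), interferon (5.16e-14), antigen presentation (6.01e-06) and acute phase lists (9.73e-04), and immediate early genes (0.179) and T cell markers (0.280) did not. No list passed there with an estimated correlation, with adjusted p = 0.831 for the neutrophil, interferon and acute phase lists and 0.842 for antigen presentation.

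**Figure D4:**
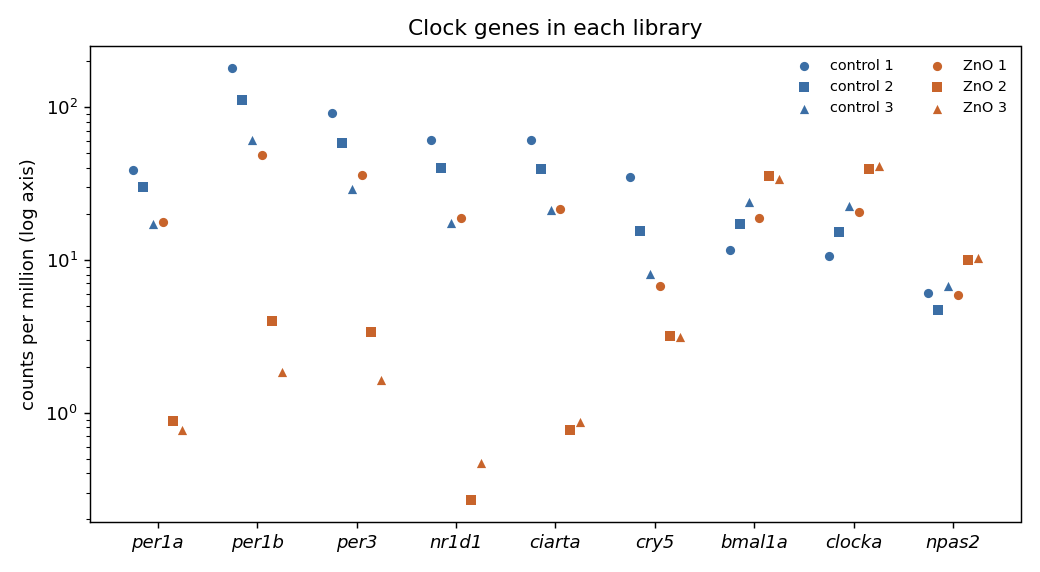
CPM on a log axis of 9 circadian clock genes in each library. per1a, per1b, per3, nr1d1 and ciarta lie at similar levels in control 3 and ZnO 1 and far lower in ZnO 2 and ZnO 3.

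Most calls of named genes were close to the threshold. Of 37, 8 passed in at least 9 of 13 alternatives, 22 in 5 to 7 and 7 in 4 or fewer (ccl19b, csf3r, mxc, c6.2, p4ha1b, col13a1 and rasgrf2b), and leaving out any 1 library except ZnO 1 ended 27 to 32 of the calls. With counts of entries that share a symbol summed, a choice made after the data were seen, 17 names were higher and 63 lower, and rasgrf2b, p4ha1b, mmp15b, ccl19b, acod1, c6.2, mxc and csf3r had edgeR adjusted p between 0.0510 and 0.0629.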

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

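The clock covariate and the summing of entries were chosen only after the results were seen, and the other alternatives in advance. None of the 37 named entries past the threshold changed direction under any alternative run on them. Higher and lower entries (25 and 86) became 419 and 772 with DESeq2 (64.8% lower), 8 and 47 with limma-voom, 122 and 283 without a filter, 16 and 47 with the stricter filter (11884 entries tested), and 14 higher both with robust=FALSE and with a minimum 2-fold change. Other scalings gave 21 to 23 higher and 80 to 82 lower. At an adjusted p under 0.01 edgeR called 0 and 0, and 0 of the fixed genes, with 4132 entries at an unadjusted p under 0.05. The clock covariate gave 0 higher, 0 lower and 0 fixed genes by edgeR, with 1714 entries at an unadjusted p under 0.05, and 14 lists; it leaves fewer residual degrees of freedom and overlaps with the group, and the cause was not tested further. Of the fixed genes 1 passed, against 5 with DESeq2 (edgeR 1). Leaving out 1 library gave 0 to 87 higher (highest without ZnO 1), 12 to 282 lower (lowest without ZnO 3), 0 to 1 fixed genes and 13 to 21 lists, with fewer samples. Lists past the set test (20) became 13 with the stricter filter, and 0 with an estimated correlation and 0 with fry. The fit with the replicate number as a block gave 3 higher, 29 lower, 0 fixed genes and 18 lists. Deviations of same-numbered libraries correlated at 0.01, -0.05 and 0.08, and 1 of 6 libraries correlated best with its own number. Over all entries this gives no sign of pairing, but 3 libraries per group cannot exclude it, and the labels do not say. The centred clock covariate fell with the replicate number in both groups (2.61, 2.01 and 1.07 in controls, 1.09, -3.24 and -3.54 in ZnO). Of the 37, 8 passed in at least 9 of 13 alternatives (gig2l, gig2l_1, klf2a, klf2a_1 and cfbl in 12, all but the covariate), 22 in 5 to 7, among them mt2, slc40a1, bcl3, nfkbiab and mmp25b in 6, and 7 in 4 or fewer: ccl19b in 2, csf3r in 3, and mxc, c6.2, p4ha1b, col13a1 and rasgrf2b in 4. The 8 hold gig2l with gig2l_1, klf2a with klf2a_1 and cfbl with cfbl_1, so they are fewer than 8 separate genes. The block ended 28 of the 37 calls and leaving out 1 library 27 to 32, except without ZnO 1, which ended 4. The GC content and length alternative was not run, because no genome of the build was used here. Depth limits entries near 3 counts, or 0.0946 to 0.113 CPM per library.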

Other observations

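The tests of symbol families, of library scaling, epidermis and leukocytes, of slc30a1a, glucocorticoid genes and gene copies, and of the clock covariate were chosen only after the results were seen, while the splits and the test of the clock output genes were set before theirs.

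Families of genes that share a symbol stem gave further groups. All 10 gig genes (median log2 fold change -1.91) and all 26 ifi genes (median -0.59), both families with interferon-induced members, were negative. Among 68 finTRIM (ftr) genes, a fish-specific family of antiviral E3 ligases, 50 were negative, and ftr43 and ftr50 fell by 0.95 and by 0.99 on the log2 scale. Proteasome subunit genes had medians of -0.29 (psmd, 15 of 16 negative), -0.30 (psma, 10 of 10) and -0.37 (psmb, 11 of 12). In the other direction, all 12 tested hoxc genes, homeobox patterning factors, were positive (median 0.46), with 0 past the edgeR threshold one by one. Of 231 families 18 passed camera with the preset correlation and 0 with an estimated correlation.

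Real and other splits of the 6 libraries were compared. The real split gave 25 higher entries and 86 lower, and the highest of the other splits 0 and 0 by edgeR, with 1 of 10 splits as large for each. With 10 splits no share under 0.05 can be reached. For lists past the set test the real split gave 20 and the highest other split, control 1 with ZnO 2 and ZnO 3, also 20, so 2 of 10 splits were as large, and the others gave 6 to 16. The number of lists past camera with the preset correlation is therefore not particular to the real split. The 20 lists were picked because they passed camera in the real split, which favours that split when their medians are compared. Of the 20, the real split gave the largest median in 11, such as neutrophil (1.02 in size against 0.604 at most in the others) and interferon (0.795 and 0.542). Margins were small for erythrocyte (1.38 and 1.35) and for Toll-like receptor and NF-kB genes (0.248 and 0.246). In the other 9 another split was as large or larger: metallothionein (0.164 and 0.345), cytokines (0.344 and 0.398), complement (0.365 and 0.423), macrophage (0.497 and 0.538), T cell (0.410 and 0.416), osteoblast (0.222 and 0.233), pigment cell (0.190 and 0.256), circadian clock (0.429 and 0.523) and immediate early (0.397 and 0.549).

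The first pattern weighed is the lower level of immune and neutrophil genes. With library totals only, all tested entries had a median of 0.0217 and the neutrophil list of -1.02, which argues against composition scaling, since that moves all entries alike (the test set beforehand, exchanging TMM for totals, is not used, as factors of 0.981 to 1.02 could move little). The osteoblast median of 0.22 (0.13 with the clock covariate) argues against a larger share of epidermis alone, which would lower all other markers alike. The mean log2 fold change of the osteoblast genes was 0.31. The SE used for a list is that of the group term of its members' mean log2 CPM per library, not of the median. For osteoblast genes it was 0.17, and 0.29 with the clock covariate. The neutrophil list, some of whose genes other leukocytes also express, had a median of -1.02 over 22 genes against -0.46 over 75 of the other leukocyte lists (permutation p = 3.2e-04 over genes, which are not independent). Per library the mean level of the neutrophil list minus that of the others was 0.41 ± 0.07 in controls and -0.27 ± 0.41 in ZnO (log2, SD, n = 3 each), lower in all ZnO libraries than in all controls, with the ZnO spread set mainly by ZnO 2 (-0.74, against 0.02 and -0.09). The nearest libraries of the groups were 0.34 apart, less than the range within ZnO, 0.766, and 3 libraries against 3 are few, so an equal loss of all leukocytes stays open. With the clock covariate the neutrophil median was -0.66 (SE of the group term of the list mean 0.21) and the interferon median -0.66 (SE of the same kind 0.53). Neither median passed its bound by more than that SE. A part played by time of collection therefore cannot be told apart from the treatment, since ZnO 1 is the only ZnO library at control-like clock levels. Lower expression per cell and an effect of the treatment, whether of the particles, the propolis extract or dissolved zinc, also stay open.

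The second pattern is the opposite shift of clock genes. The period, nr1d and output genes had a median log2 fold change of -1.20 (13 of 17 negative), while all 6 bmal, clock and npas2 genes were positive (median 0.66). The prediction for groups collected at different times of day, a median below -0.3, was met, but this bound took no account of spread. None of the 17 genes passed by edgeR (lowest adjusted p = 0.333). The centred clock covariate was 1.07 in control 3 and 1.09 in ZnO 1, against -3.24 and -3.54 in ZnO 2 and ZnO 3. Different times of collection could give such shifts, and control 3 and ZnO 1 would then be closest in time. The labels used here give no collection times, and an effect of the treatment on the clock itself may give the same shifts.

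The third pattern is the higher level of mt2. With copies summed its log2 fold change was 1.76, so divided reads do not account for it. The 95% interval of slc30a1a, another target of the metal-responsive factor, ran from -0.62 to -0.0020. With the replicate block and with each library left out its upper end was at most 0.094, the value without ZnO 3, where the log2 fold change of -0.31 moved to -0.19. With the clock covariate the log2 fold change was -0.07 and the interval reached 0.387. Because of that fit a zinc response of the whole tissue stays open on this 1 gene. The median of 5 glucocorticoid-responsive genes was -1.45 ± 0.79 (SE of the group term) and -0.45 ± 0.73 with the covariate, so glucocorticoid signalling stays open too. With the clock covariate mt2 was at 1.495 ± 0.31 against 1.78 ± 0.21 without, and the call ended (adjusted p = 0.451, range over alternatives 1.4e-10 to 0.451) as the SE grew and the estimate fell. The call ended in 7 of 13 alternatives, also with the replicate block (edgeR adjusted p = 0.0697) and without any 1 library except ZnO 1 (edgeR adjusted p 0.0526 to 0.0867, log2 fold changes of at least 1.56), so its loss is not particular to the covariate; a time-of-day difference cannot be told apart from the treatment here, and a local metal response may remain.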
